A study of Mus musculus with 23 samples.

How the data were processed

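The study measured polyadenylated RNA by strand-specific mRNA-seq in mouse embryonic stem (ES) cells grown on gelatin with serum and LIF, per the labels' protocols. The 23 samples formed 11 groups in 3 series. The genetic series held AB2.2 wild type (n = 2), the Ago1,3,4-null line B9 (n = 2), the line E7, null for all 4 mouse Argonautes and carrying a floxed human Ago2 transgene (n = 3), and 2 clones without any Argonaute, C62 and C86 (n = 2). The mutant lines were also Blm-null. The time course and the rescue used TT-FHAgo2 cells, which lack the 4 endogenous Argonautes and carry a doxycycline-inducible Ago2. For the time course the cells were held at 2.5 µg/mL doxycycline for 48 h, a dose that gives the wild-type level of Ago2 per the labels' protocols, and then kept without it for 0, 24, 48 or 96 h (n = 2 each). For the rescue they spent 96 h without doxycycline (n = 2) or 96 h without it and then 48 h at 0.1 or 2.5 µg/mL (n = 2 each). By the labels the dosed groups were thus 48 h longer in culture than their control. In the time course the 24, 48 and 96 h groups were likewise 24, 48 and 96 h longer in culture than the 0 h group.

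The authors deposited 6 tables, with exons and introns of each series apart, for 18412 genes. Each column holds the signal of 1 group: the authors' mean of normalised reads over its libraries, per the file headers. Per the submitters' processing notes, TopHat2 2.0.12 and DESeq were used with the mouse build mm10. The version of DESeq, the read counter and the gene annotation are not given in the sources used here.

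No table held separate libraries, so library values were worked out from the group means. Each deposited mean is a sum of whole read numbers, each multiplied by 1 step per library, the step being the inverse of that library's size factor times the number of libraries. The steps were found from the smallest values of each column. Every value was then searched for whole read numbers that give it at the deposited precision. A single solution was found for 405027 of 405064 values (99.991%), with a largest relative misfit of 5.33e-15. The 37 others were all in E7, where 3 libraries were averaged. In the E7 exon column 36 abundant genes had no single solution. They hold 10.3% of the summed E7 exon mean and were left out of tests in the genetic series. Peg10 and Aldoa are among them, so some lists have fewer members there than in the time course. Size factors refitted from the recovered reads by medians of ratios were 0.986 to 1.024 times the recovered ones. Tested on simulated data, the search returned every value of a group of 2 libraries and 99.728% of those of a group of 3, with 0 wrong. Libraries are numbered by depth within their group, because the columns carry no replicate number. Which library is which deposited sample, and which clone library is C62 or C86, is therefore unknown.

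Exon reads per library were 13.5 to 53.7 M in the genetic series, 32.9 to 62.4 M in the time course and 24.7 to 53.8 M in the rescue. E7 depths are without the 36 genes, and intron shares in the genetic series use genes solved in every library. The median absolute log2 difference between libraries of 1 group was 0.269 to 0.539 in the genetic series, 0.0633 to 0.0843 in the time course and 0.0698 to 0.0919 in the rescue. The median standard error of a log2 change was 0.336 to 0.368, 0.0797 and 0.0910 in the 3 series. Simulated data gave every gene of a series the same spread, that typical of its most abundant genes over all groups. In the genetic series this was an SD of 0.28 on the log2 scale. For clones against E7, 8% of exon changes of 1.5-fold, 54% of 2-fold and 100% of 4-fold were then called. The 2 clone libraries differed by a median of 0.539, the most of any group, and these shares do not describe that spread. For 24 h against 0 h, with an SD of 0.0431, 93.9% of 1.5-fold and 98% of 2-fold changes were called. For 0.1 µg/mL against no doxycycline, with an SD of 0.0453, 86% and 98% were called. Of the genes called in these simulations of exons, 2.24, 10.1 and 6.4% were false.

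Normalised reads of each library kept the authors' size factors. They were raised by 1, put on the log2 scale and tested with limma 3.58.1 in R 4.3.3, with a trended prior, in 1 fit per table over all its groups. Genes with a mean of at least 10 normalised reads over the libraries of a series were tested, and a gene was called at a Benjamini-Hochberg adjusted p below 0.05 within its comparison. The design had named a test for deposited library values; for group means of this unit the same fit was run on the recovered values. Tables of different series were normalised apart and were compared only through changes within a series. There were 12 comparisons in exon tables. Intron tables were tested alike, and exon minus intron log2 values, centred per library, were tested to set apart changes after transcription from changes in unspliced RNA. Exon and intron libraries of a group were matched by the correlation of their deviations from the group mean. It was 0.359 to 0.616 in the genetic series, 0.056 to 0.167 in the time course and 0.029 to 0.085 in the rescue. The match was thus weak in the time course and the rescue. Exon minus intron and the intron share of a library, with the library sets drawn from it, rest on this match. Fold changes are ratios of group means, log2 changes are those of the fit, and the added 1 makes the latter smaller for genes with few reads. A fold against a group with 0 reads is given as a lower bound from 3 reads pooled over that group.

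Genes were grouped in 26 lists written from general knowledge. These lists, the rule for naming genes and all tests not described below as chosen later were fixed before the data were examined. The lists were Argonaute and microRNA machinery, known targets of ES-cell microRNAs (published direct targets of the miR-290 and miR-17 families), microRNA host transcripts, Smad2/3 targets, BMP-Smad1/5 targets and Tgf-β pathway components. Lists of cell states covered naive pluripotency, formative and primed pluripotency, primitive endoderm, mesoderm and primitive streak, neuroectoderm, trophoblast, fibroblast feeder, the 2-cell-like state, germline and imprinted genes. The remaining lists were extracellular matrix and cytoskeleton, p53 targets, interferon response, integrated stress response (Atf4 targets), mitochondrially encoded genes, cholesterol biosynthesis, glycolysis and hypoxia, G1/S regulators, immediate early genes and replication-dependent histones. Lists with at least 5 measured members were tested with camera of limma at a preset correlation between genes of 0.01, adjusted over the 24 lists that reached this size, and again with the correlation estimated from the data. Members were counted as risen or fallen by the call in the whole table, and again with p adjusted over the list alone. Some genes sit in several lists. Lefty1, Lefty2 and Cdkn1a are in both known targets and Smad2/3 targets, Tgfb1, Gdf3 and Nodal in Smad2/3 targets and pathway components, and Lats2 and Rbl2 in known targets and G1/S regulators.

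Seed sites of 9 microRNA families were counted in annotated 3' UTRs of GENCODE mouse release 21 on mm10. Of the 18412 genes 18329 matched this annotation and 18083 had a 3' UTR of at least 30 bases. A site was a match to either 7-mer of the seed, and an 8-mer match holds both. The families, named by 1 member, were miR-290 (with miR-302), miR-17 (with miR-20, miR-93 and miR-106), miR-130 (with miR-301), miR-19, miR-25 (with miR-92) and miR-15 (with miR-16), with let-7, miR-122 and miR-124 as controls chosen for low presence in ES cells. The seed shift is the median log2 change of genes with a site minus that of genes without, tested with camera and adjusted over the 9 families of a comparison (an adjustment added after the data were seen). A matched shift compares genes within 20 bins of 3' UTR length. Sites of miR-290 and miR-17 share sequence, so these gene groups overlap.

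The rule for genes named in the text takes Ago1 to Ago4 and Blm, and per comparison up to 6 of the largest rises and falls among called genes with a mean of at least 50, libraries that do not overlap between groups, and an established symbol. It adds up to 4 called members of each list (the 2 with the highest mean where none was called), up to 8 genes per direction called both at 96 h and in clones against E7, and up to 5 per direction for exon minus intron. Comparisons against the same control libraries share chance values. Their correlations were therefore set beside 50 simulated draws without an effect, made from the spread of the libraries.

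Alternatives tried were an added 8 in place of 1, no filter or a mean of at least 50, quantile normalisation, a fit with only the libraries compared, a 2-fold threshold, limma-voom on the recovered reads, and leaving out each library in turn. For lists, the fry test and an estimated correlation were tried, and for correlations, Pearson in place of Spearman. Chosen after the data were seen were limma-voom, fits without libraries of high or low intron share, fits without the clones or without genes of chromosomes 8 and Y, and the other match of exon and intron libraries. A fit with that library set as a term, also chosen then, left out the clones too. Figures were drawn with matplotlib 3.10.9; tables were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and numba 0.67.0. Raw reads, small RNA and protein were not analysed here. Some genes that the naming rule picks are not reported here. Reads over single exons, and with them the deletions themselves and the human Ago2 transgene, were also not analysed here.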

Results

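Exon and intron reads of 23 libraries were compared in 3 series: 4 genotypes (n = 2 or 3), 4 times after removal of doxycycline (n = 2 each) and 3 doses of it given back (n = 2 each). Wild-type libraries had 46.5 and 13.5 M exon reads, B9 29.2 and 26.5, E7 24.1, 20.7 and 17.7, and the clones 53.7 and 19.5. The time course had 50.1 and 44.3 M at 0 h, 45.1 and 32.9 at 24 h, 62.4 and 58.0 at 48 h, and 48.7 and 47.0 at 96 h. The rescue had 34.6 and 31.9 M without doxycycline, 27.9 and 24.7 at 0.1 µg/mL, and 53.8 and 45.0 at 2.5 µg/mL. Values are mean normalised reads with SD over libraries. Log2 changes come with their standard error (SE) and the adjusted p of limma. Genes of the genetic series were measured with a median SE of 0.336 to 0.368, against 0.0797 in the time course and 0.0910 in the rescue. Fewer calls among genotypes therefore do not show smaller changes. All time course and rescue libraries came from TT-FHAgo2 cells, so tests there measure the spread of libraries and not of lines.

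The targeted genes were read first. Ago1 (ENSMUSG00000041530, chromosome 4, 126435012 to 126468583, mm10) had 4104 ± 834 normalised reads in wild type (n = 2) and 0 reads in every library of B9, E7 and the clones, at least 3862-fold lower in the clones (adjusted p = 0.000238). In B9 it was at least 2851-fold lower (adjusted p = 0.00108); the call, though not the absence of reads, was lost without wild-type library 2 (adjusted p = 0.108). TT-FHAgo2 libraries also had 0 reads of Ago1. Ago2 (ENSMUSG00000036698, chromosome 15, 73095844 to 73184935) had 6227 ± 1452 exon reads in wild type, 6734 ± 1214 in B9, 5209 ± 1611 in E7 and 5819 ± 877 in the clones, so its gene-wide exon reads do not show its deletion. Its intron reads were 206 ± 127 in wild type, 1239 ± 92.6 in E7 (log2 change 2.73, SE 0.41, adjusted p = 0.0119) and 1661 ± 366 in the clones (3.13, adjusted p = 0.00292). In TT-FHAgo2 cells Ago2 exon reads were 11963 ± 288 at 0 h, 11420 ± 117 at 24 h (not called) and 10794 ± 32.6 at 96 h (log2 change -0.15, SE 0.04, adjusted p = 0.00354). They were 7280 ± 28.5 without doxycycline and 5689 ± 572 at 2.5 µg/mL (-0.36, SE 0.05, adjusted p = 1.83e-06), so gene-wide reads of Ago2 did not follow the dose. Ago3 (ENSMUSG00000028842, chromosome 4, 126331704 to 126429556) was not called among genotypes, with 487 ± 170 in wild type, 1447 ± 172 in B9, 1523 ± 389 in E7 and 1362 ± 1109 in the clones, so its gene-wide reads do not show its deletion either. It went from 4533 ± 180 at 0 h to 2181 ± 89.8 at 96 h (log2 change -1.06, SE 0.06, adjusted p = 1.95e-13). Ago4 (ENSMUSG00000042500, chromosome 4, 126489541 to 126533472) was close to silent throughout, at 33.0 ± 13.2 in the rescue without doxycycline. Blm (ENSMUSG00000030528, chromosome 7, 80454733 to 80535119), the helicase gene disrupted in the mutant lines, had 4808 ± 956 in wild type and 1569 ± 670 in the clones (log2 change -1.67, SE 0.31, adjusted p = 0.00529), a call lost without wild-type library 2. It had 3431 ± 384 in B9 and 2695 ± 341 in E7. Gene-wide reads of Blm thus remained in all mutant lines and do not by themselves show its disruption.

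Removing doxycycline for 96 h asks what changes when the only Argonaute of the cell is meant to be lost. Lefty1, the feedback inhibitor of Nodal, rose 6.67-fold, from 4150 ± 118 to 27688 ± 7.19 (n = 2 and 2; log2 change 2.74, SE 0.04, adjusted p = 3.68e-24). The cell-cycle inhibitor Cdkn1a rose 5.35-fold, from 1853 ± 4.95 to 9916 ± 118 (2.42, SE 0.05, adjusted p = 2.11e-21). Lin28a, which blocks let-7 maturation, fell 8.64-fold, from 31189 ± 224 to 3609 ± 95.5 (-3.11, SE 0.04, adjusted p = 7.35e-25). Of 13652 genes tested 8867 were called, 4426 higher and 4441 lower, and 1829 changed at least 2-fold, 1178 of them upward. The largest rises were those of the interferon regulatory factor Irf2 (33.7-fold, to 338; log2 change 5.01), the nucleic acid sensor Zbp1 (4.82), the chitinase Chit1 (4.45), the lipoxygenase Alox12e (4.04) and Megf11 (131 to 2151; 4.04). The largest falls were those of the acetylcholine transporter Slc18a3 (247 to 8.85; -4.72), Spink1 (-4.34), Vrtn (-4.16), the metalloproteinase Mmp28 (154 to 8.88; -3.98) and Magel2 (-3.93). On mm10 these include Irf2 (ENSMUSG00000031627, chromosome 8, 46739732 to 46847458), Zbp1 (ENSMUSG00000027514, chromosome 2, 173206612 to 173218923), Megf11 (ENSMUSG00000036466, chromosome 9, 64385626 to 64709205) and Mmp28 (ENSMUSG00000020682, chromosome 11, 83440768 to 83463071). Further positions are Lefty1 (ENSMUSG00000038793, chromosome 1, 180935022 to 180938400), Lefty2 (ENSMUSG00000066652, chromosome 1, 180893108 to 180899103), Cdkn1a (ENSMUSG00000023067, chromosome 17, 29090976 to 29100727) and Lin28a (ENSMUSG00000050966, chromosome 4, 134003330 to 134018841).

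Known targets of ES-cell microRNAs rose together at 96 h. Of 19 members measured 18 rose, 0 fell and 1 did not pass, with 19 risen adjusted over the list alone (median log2 change 1.17; camera adjusted p = 1.42e-11, adjusted p = 0.0345 with an estimated correlation). Examples are the Hippo kinase Lats2 (ENSMUSG00000021959, chromosome 14, 57689662 to 57758388), from 665 ± 31.4 to 2504 ± 303 (1.91, SE 0.09), the pocket protein Rbl2 (ENSMUSG00000031666, chromosome 8, 91070057 to 91123844; 1127 to 4033, 1.84), the nuclear receptor Nr2f2 (63.6 to 452, 2.81) and the antiproliferative Btg2 (1697 to 5907). The type II Tgf-β receptor Tgfbr2, also a member, rose from 111 to 514. In introns the median of the list was 0.26. Among the Argonaute and microRNA machinery, 2 of 14 rose, 4 fell and 8 did not pass, with the same 2 and 4 adjusted over the list alone (camera adjusted p = 0.401). The silencing scaffolds Tnrc6a (11027 to 16385, 0.57) and Tnrc6b (8314 to 14355, 0.79) were the risen ones.

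Smad2/3 targets rose as a list at 96 h, which bears on the Tgf-β/Smad network the series is about. Of 21 members 15 rose, 0 fell and 6 did not pass, with 16 risen and 2 fallen adjusted over the list alone (median 0.54; camera adjusted p = 3.72e-06, adjusted p = 0.148 with an estimated correlation). Lefty2 rose from 4362 ± 190 to 24943 ± 2250 (log2 change 2.51, SE 0.05, adjusted p = 3.75e-21), the circadian repressor Bhlhe40 from 717 to 4264 (2.54) and the streak gene Gsc from 23.1 to 91.1 (1.93). In introns the list median was 0.54. Of 23 Tgf-β pathway components 15 rose, 2 fell and 6 did not pass, with the same 15 and 2 adjusted over the list alone (median 0.34; camera adjusted p = 0.00452, adjusted p = 0.207 with an estimated correlation). The activin subunit Inhbb rose from 4173 to 10604 (1.35), whereas the BMP ligand Bmp4 fell from 1126 to 336 (-1.74). Of 11 BMP-Smad1/5 targets 4 rose, 3 fell and 4 did not pass, as when adjusted over the list alone (camera adjusted p = 0.441). Id4 (768 to 1613, 1.07) and Msx2 (84.5 to 274, 1.70) rose and the BMP antagonist Nog fell (39.8 to 10.9, -1.82).

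Targets of Atf4 fell at 96 h. Of 20 integrated stress response genes 17 fell, 1 rose and 2 did not pass, the same adjusted over the list alone (median -0.89; camera adjusted p = 3.71e-07, adjusted p = 0.148 with an estimated correlation). The glutathione-degrading enzyme Chac1 (ENSMUSG00000027313, chromosome 2, 119351229 to 119354381) fell from 1342 ± 21.1 to 281 ± 32.3 (SE 0.12, adjusted p = 6.22e-14). The cystine transporter Slc7a11 fell from 146 to 16.8 (-3.06) and the folate enzyme Aldh1l2 from 669 to 202 (-1.75). Interferon genes moved the other way, 11 of 13 risen and 2 fallen, also adjusted over the list alone (median 0.96; camera adjusted p = 0.00434, adjusted p = 0.148 with an estimated correlation), with Ifit1 (7.02 to 91.3, 3.58) and Oasl2 (17.1 to 135, 2.90) among them. Of 21 cholesterol genes 15 rose, 4 fell and 2 did not pass, the same adjusted over the list alone (median 0.29; camera adjusted p = 0.00434, adjusted p = 0.503 with an estimated correlation). The sterol regulator Insig1 (3354 to 5308, 0.66) was among the risen. Of 18 p53 targets 11 rose, 2 fell and 5 did not pass, the same adjusted over the list alone (median 0.39; camera adjusted p = 0.00452, adjusted p = 0.379 with an estimated correlation), for example Perp (961 to 2178, 1.18). Of 22 G1/S regulators 14 rose, 5 fell and 3 did not pass, with 15 and 5 adjusted over the list alone (median 0.39; camera adjusted p = 0.019, adjusted p = 0.322 with an estimated correlation), and Myc fell from 2957 to 1016 (-1.54).

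**Figure D1:**
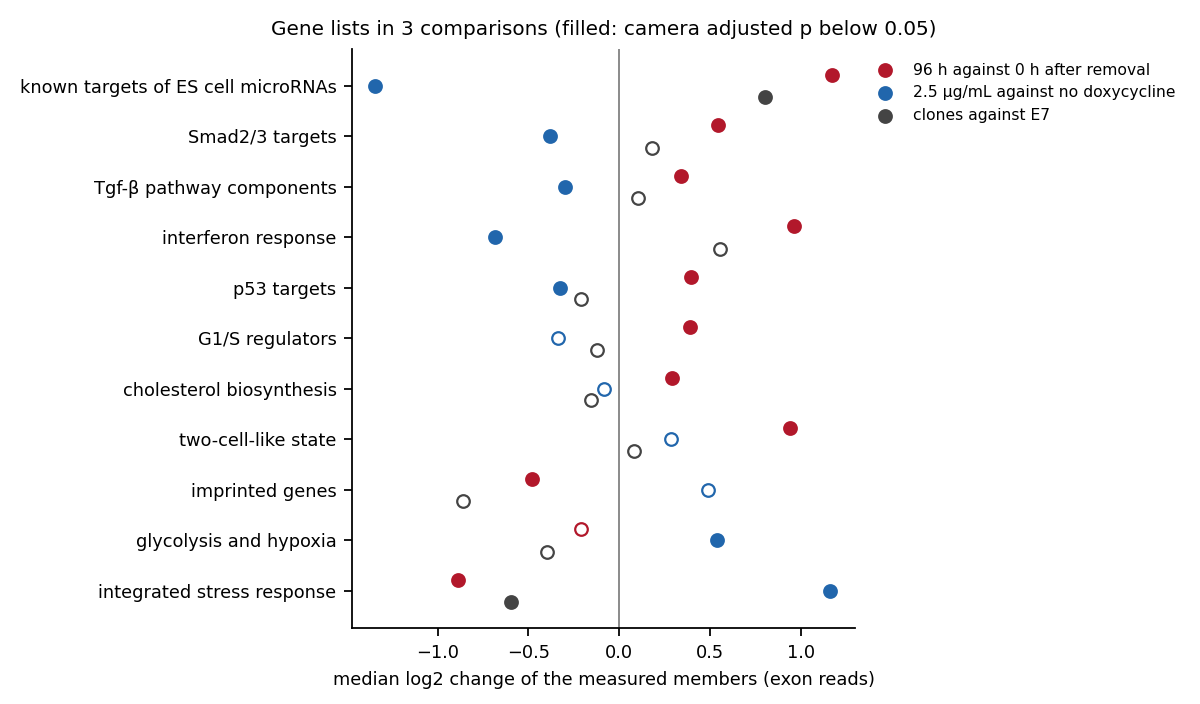
Median log2 change of 11 gene lists at 96 h against 0 h (red), at 2.5 µg/mL against no doxycycline (blue) and in clones against E7 (black). Filled points have a camera adjusted p below 0.05.

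Cell-state lists at 96 h were mostly mixed. Of 10 genes of the 2-cell-like state 9 rose, 0 fell and 1 did not pass, the same adjusted over the list alone (median 0.94; camera adjusted p = 0.0159, adjusted p = 0.278 with an estimated correlation), for example Zscan4f (467 to 1174, 1.33) and Usp17la (53.1 to 177, 1.72). Of 15 imprinted genes 2 rose, 10 fell and 3 did not pass, the same adjusted over the list alone (median -0.48; camera adjusted p = 0.019, adjusted p = 0.278 with an estimated correlation). The retrotransposon-derived Peg10 fell from 76313 to 29267 (-1.38), while the zinc-finger gene Plagl1 rose from 4054 to 16977 (2.07). Of 22 naive pluripotency genes 8 rose and 12 fell (camera adjusted p = 0.664), with Klf2 up (31529 to 74141, 1.23) and Nr0b1 down (20384 to 10431, -0.97). Of 10 formative and primed genes 3 rose and 6 fell (camera adjusted p = 0.274), Otx2 (1481 to 2692, 0.86) against Dnmt3b (10516 to 4498, -1.23) and Pou3f1 (562 to 188, -1.58). Of 13 primitive endoderm genes 5 rose and 4 fell (camera adjusted p = 0.486), Gata4 (114 to 272, 1.25) against Sox7 (163 to 12.8, -3.56). In mesoderm and streak 4 rose and 1 fell of 10 (camera adjusted p = 0.531), with Evx1 (91.5 to 348, 1.92) and the Vegf receptor Kdr (95.7 to 322, 1.74) up. In trophoblast 4 rose and 3 fell of 10 (camera adjusted p = 0.787), Krt19 (173 to 1127, 2.69) against Ascl2 (242 to 48.1, -2.32). In germline 4 rose and 12 fell of 16 (camera adjusted p = 0.0642), the latter with the meiotic Sycp3 (230 to 60.7, -2.00). Adjusted over the list alone, none of these 6 lists changed its counts.

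Structural, metabolic and other lists at 96 h did not pass. Of 27 matrix and cytoskeleton genes 15 rose and 8 fell (15 and 9 adjusted over the list alone; camera adjusted p = 0.1), the integrin Itgav (2979 to 10078, 1.76) and Thbs1 (103 to 415, 1.99) against the myosin light chain Myl9 (348 to 99.6, -1.81). Of 21 glycolysis and hypoxia genes 7 rose and 11 fell (camera adjusted p = 0.262), with a median of -0.21 and a mean of 0.04 that differ in sign. The prolyl hydroxylase Egln3 rose (922 to 2588, 1.45) and Aldoa fell (63226 to 36569, -0.80). Of 15 immediate early genes 8 rose and 5 fell (camera adjusted p = 0.257), for example Fosb (43.2 to 181, 2.06). Of 7 neuroectoderm genes 2 rose and 2 fell (camera adjusted p = 0.934), Nes (1154 to 2551, 1.14) against Sox11 (-0.89). Of 7 feeder genes 2 rose and 1 fell (camera adjusted p = 0.664), including S100a6 (1313 to 1888, 0.52). Of 10 replication-dependent histones 0 rose and 1 fell, with 0 adjusted over the list alone (camera adjusted p = 0.692). The fall of Hist2h2be (-0.54, adjusted p = 0.0452) was lost without 0 h library 1 (adjusted p = 0.0731), 0 h library 2 (0.178) or 96 h library 2 (0.198). The other 4 lists kept their counts adjusted over the list alone. Of 10 microRNA host transcripts 1 was in the tables and of 13 mitochondrially encoded genes 0, too few to test.

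The 24 and 48 h points ask which changes came early. At 24 h the stanniocalcin gene Stc1 rose from 7.40 ± 5.0 to 141 ± 27.0 (n = 2 and 2; log2 change 4.21, SE 0.45, adjusted p = 4.86e-08) and the metallothionein Mt2 fell from 16153 ± 195 to 3444 ± 231 (-2.23). Of 13652 genes 6919 were called (3624 higher) at 24 h and 8642 (4378 higher) at 48 h. At 24 h 19 of 20 integrated stress response genes fell and 1 rose, the same adjusted over the list alone (median -0.72; camera adjusted p = 3.07e-12, adjusted p = 0.0823 with an estimated correlation), and Chac1 was down to 307. Of 21 glycolysis and hypoxia genes 16 rose and 1 fell (median 0.47; camera adjusted p = 6.25e-07, adjusted p = 0.336 with an estimated correlation), with Egln3 at 2690.2 and the mitophagy receptor Bnip3 going from 3249 to 7563. The cholesterol list also rose early, 17 of 21 risen and 0 fallen (median 0.33; camera adjusted p = 7.24e-07, adjusted p = 0.33 with an estimated correlation). Of 19 known targets 14 rose and 2 fell, 16 and 2 adjusted over the list alone (median 0.47; camera adjusted p = 8.86e-07, adjusted p = 0.0823 with an estimated correlation). Lefty1 was at 13145 ± 105 (1.66), Cdkn1a at 4496 ± 174 (1.28) and Lin28a at 22983 ± 648 (-0.44). Of 21 Smad2/3 targets 13 rose and 5 fell (median 0.25; camera adjusted p = 0.00503, adjusted p = 0.278 with an estimated correlation), with Bhlhe40 up at 3238 and the inhibitory Smad7 down from 6920 to 4719 (-0.55). The glycolysis, cholesterol and Smad2/3 counts at 24 h were the same adjusted over the list alone. At 48 h all 19 known targets had risen, also adjusted over the list alone (median 0.84; camera adjusted p = 2.87e-10, adjusted p = 0.0433 with an estimated correlation). Lefty1 stood at 29631 ± 196 (2.84), Irf2 at 114 (3.45) and Insig1 at 8621 ± 74.3 (1.36).

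From 24 to 96 h, 7818 genes were called (4023 higher), a comparison that asks what continued or turned back. Evx1 rose from 12.9 to 348 (log2 change 4.72), Nr2f2 from 32.8 to 452 (3.80) and Lats2 from 521 to 2504 (2.26). The growth cone gene Gap43 (ENSMUSG00000047261, chromosome 16, 42248442 to 42340651) fell from 1642 to 98.9 (-4.04) and Matn3 from 172 to 7.46 (-4.43). Of 19 known targets 16 rose further and 0 fell, also adjusted over the list alone (median 0.85; camera adjusted p = 1.02e-09, adjusted p = 0.0481 with an estimated correlation). The glycolysis and hypoxia list turned back, 17 of 21 fallen and 1 risen, the same adjusted over the list alone (median -0.55; camera adjusted p = 5.88e-08, adjusted p = 0.47 with an estimated correlation). Changes at 24 and 96 h share the 0 h libraries; across genes, which are not independent replicates, their rank correlation was 0.547, against 0.445 in simulated draws without an effect. Their covariance was 0.231 against 0.0231 simulated.

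**Figure D2:**
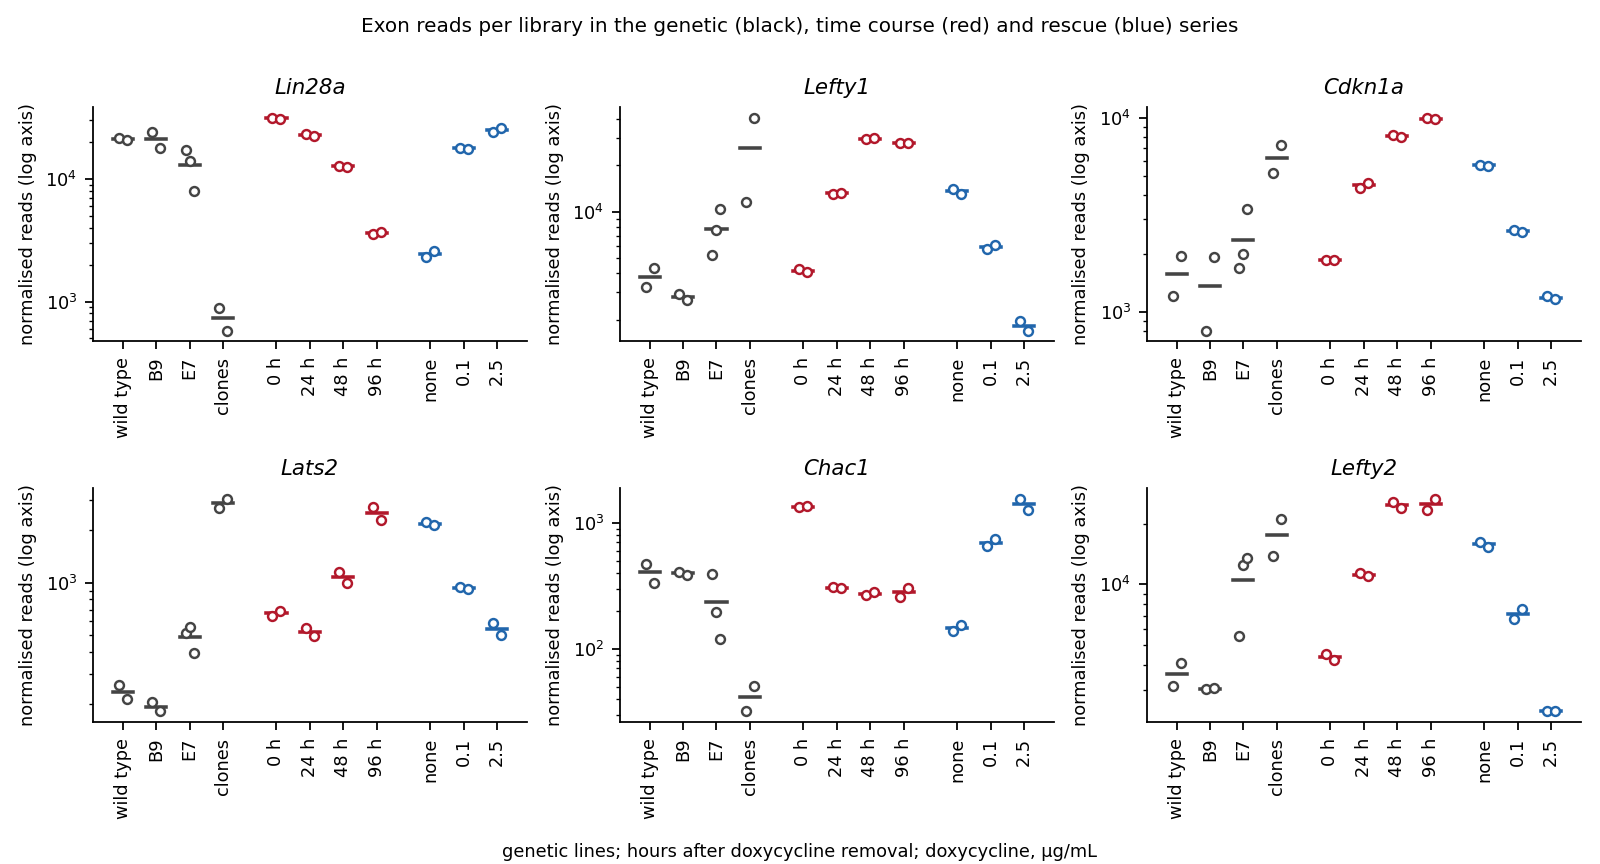
Normalised reads of Lin28a, Lefty1, Cdkn1a, Lats2, Chac1 and Lefty2 in each library (points) with group means (bars), for the genetic series (black), the time course (red) and the rescue (blue).

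Giving doxycycline back asks which of these changes return with Ago2. At 2.5 µg/mL Lin28a rose 10.3-fold, from 2430.1 ± 188 to 25057 ± 1158 (n = 2 and 2; log2 change 3.37, SE 0.05, adjusted p = 1.66e-26). Lefty1 fell 7.42-fold, from 13521 ± 645 to 1823 ± 178 (-2.89, SE 0.06, adjusted p = 1.13e-23), and Cdkn1a from 5692 ± 71.5 to 1184 ± 29.97 (-2.26). The largest rise was that of Mmp28, 61.4-fold from 1.97 ± 2.79 to 121 ± 14.7 (5.77, SE 0.58, adjusted p = 1.71e-09), then Magel2 (6.28 to 168), Spink1 (4.43) and Usp51 (4.21). The largest falls were the interferon-stimulated Oasl2 (126 to 2.10, -5.38), Irf2 (262 to 7.495, -5.09) and Ifit1 (105.8 to 4.57, -5.06). Of 13176 genes 8400 were called, 4189 higher and 4211 lower, and 1883 at least 2-fold, 750 upward and 1133 downward. Both 2.5 µg/mL libraries had an intron share of 8.64 and 8.29%, against 11.97 to 12.5% in the other 4, so dose and intron share cannot be separated in this comparison. Nor can dose and the 48 h of further culture that, by the labels, the dosed groups had.

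Several lists moved with the dose opposite to 96 h, and others did not. At 2.5 µg/mL 18 of 19 known targets fell and 0 rose, also adjusted over the list alone (median -1.34; camera adjusted p = 1.71e-11, adjusted p = 0.1 with an estimated correlation), among them Lats2 (2185 ± 64.9 to 543 ± 59.5, -2.01), Rbl2 (3000.3 to 414, -2.86) and Nr2f2 (345 to 36.0, -3.24). Of 21 Smad2/3 targets 16 fell and 3 rose, the same adjusted over the list alone (median -0.38; camera adjusted p = 0.000351, adjusted p = 0.166 with an estimated correlation), with Lefty2 down from 15767 ± 515 to 2346 ± 0.808 (-2.75). Of 22 Tgf-β components 15 fell and 4 rose, the same adjusted over the list alone (median -0.30; camera adjusted p = 0.0144, adjusted p = 0.295 with an estimated correlation), among them Tgfbr2 (361 to 66.4, -2.43) and Bmpr2 (-1.17). Of 20 integrated stress response genes 19 rose and 0 fell, also adjusted over the list alone (median 1.16; camera adjusted p = 6.14e-12, adjusted p = 0.1 with an estimated correlation), with Chac1 up from 147 ± 12.3 to 1410.2 ± 204 (3.25, SE 0.12) and the serine enzyme Phgdh from 1461 to 5747 (1.98). Of 21 glycolysis genes, a list that did not pass at 96 h, 13 rose and 3 fell, the same adjusted over the list alone (median 0.54; camera adjusted p = 0.000511, adjusted p = 0.546 with an estimated correlation). Of 13 interferon genes 10 fell and 2 rose, the same adjusted over the list alone (median -0.68; camera adjusted p = 0.0298, adjusted p = 0.301 with an estimated correlation). Of the lists that passed at 96 h, 4 did not pass at 2.5 µg/mL: the 2-cell-like (3 of 11 risen, 0 fallen; camera adjusted p = 0.413), imprinted (10 of 15 risen, 3 fallen; 0.0996), cholesterol (7 of 21 risen, 10 fallen; 0.413) and G1/S lists (6 of 22 risen, 12 fallen; 0.0598). Their counts were the same adjusted over the list alone. The intron share of these libraries, 8.64 and 8.29%, stands beside these lists as well.

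At 0.1 µg/mL 5808 genes were called (2900 higher) and the genes named here lay between the other groups. Lefty1 was at 5933 ± 246 (n = 2; log2 change -1.19 from no doxycycline), Lats2 at 932 (-1.23) and Lin28a at 17706 ± 384 (2.87, adjusted p = 1.07e-24). Of 19 known targets 18 fell and 0 rose, also adjusted over the list alone (median -0.73; camera adjusted p = 2.41e-12, adjusted p = 0.0947 with an estimated correlation). Between 0.1 and 2.5 µg/mL 5403 genes were called (2639 higher). Known targets fell further, 15 of 19 fallen and 1 risen, with 16 and 1 adjusted over the list alone (median -0.62; camera adjusted p = 1.03e-11, adjusted p = 0.076 with an estimated correlation). Irf2 went from 93.01 to 7.495 (-3.57), Rbl2 from 1364 to 414 (-1.72) and the estrogen receptor Esr1 from 314 to 33.6 (-3.23).

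Clones against E7 asks about loss of the last Argonaute by recombination, without doxycycline. Lats2 rose 5.86-fold, from 487 ± 83.6 (n = 3) to 2856 ± 249 (n = 2; log2 change 2.56, SE 0.27, adjusted p = 0.0027). Lin28a fell 17.8-fold, from 13052 ± 4605 to 735 ± 221 (-4.11, SE 0.32, adjusted p = 0.000549), and Gap43 142-fold, from 653 ± 415 to 4.597 ± 1.05 (-6.59, SE 0.61, adjusted p = 0.000969). The phospholipase Pla2g1b (551 ± 134 to 23.7 ± 13.7, -4.58), the neuroendocrine factor Insm1 (-4.31) and the kallikrein Klk8 (-4.20) also fell, and these 6 calls held without any 1 library. Of 13207 genes 198 were called, 94 higher and 104 lower, but the count ranged from 15 without E7 library 2 to 2146 without clone library 1, with 69 without E7 library 1 and 62 without clone library 2. Nor was the direction of the split stable, with 187 higher and 89 lower by limma-voom, 157 and 115 with 8 added, and 126 and 101 without E7 library 3. The tryptophan dioxygenase Ido2 (ENSMUSG00000031549, chromosome 8, 24531892 to 24576333) rose from 5.92 ± 6.67 to 1297 ± 961 (8.01, SE 1.08, adjusted p = 0.00835), a call lost without clone library 2 (adjusted p = 0.0508). Both clone libraries had a low intron share, 10.46 and 7.489%, against 13.27 and 13.21% in E7 libraries 2 and 3 and 8.681% in E7 library 1, so genotype and intron share go partly together here. Lefty1 was at 7734 ± 2544 in E7 and 25941 ± 20420 in the clones and was not called (adjusted p = 0.112). In introns 15 genes were called, 2 higher and 13 lower, with Pla2g1b (1515 to 85.8, -4.26) among the latter; the count was 8, 2 and 6 without E7 library 1, 2 and 3, and 74 and 9 without clone library 1 and 2.

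In clones against E7 2 of 19 known targets rose and 0 fell, with 8 and 0 adjusted over the list alone (median 0.80; camera adjusted p = 0.000361, adjusted p = 0.657 with an estimated correlation). Besides Lats2 the other was Rbl2 (683 ± 158 to 2143 ± 544, 1.65, adjusted p = 0.0251), lost without E7 library 1 (adjusted p = 0.0769) or E7 library 2 (0.124). Of 20 integrated stress response genes 1 fell and 0 rose, with 7 fallen adjusted over the list alone (median -0.59; camera adjusted p = 0.00109, adjusted p = 0.787 with an estimated correlation). That gene was Chac1 (237 ± 140 to 41.3 ± 13.3, -2.36, adjusted p = 0.04), lost without E7 library 1 (adjusted p = 0.0996), E7 library 2 (0.156) or clone library 2 (0.0973). Without clone library 1 neither list passed (adjusted p = 0.171 and 0.654). Of 21 Smad2/3 targets limma called 0, with 7 at an unadjusted p below 0.05 (median 0.18; camera adjusted p = 0.283), and of 23 Tgf-β components 0, with 4 at an unadjusted p below 0.05 (median 0.10; camera adjusted p = 0.481). Rbl2 and Ido2 lie on chromosome 8, whose genes were higher in the clones as a whole (median log2 difference 0.344 from the other chromosomes).

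The clones were also compared with wild type and with B9, each of which is 1 line. They differ from wild type in Blm as well. Against wild type (n = 2 and 2) Lats2 rose 12.1-fold, from 236 ± 29.9 to 2856 ± 249 (log2 change 3.60, SE 0.29, adjusted p = 0.000238), Lefty2 from 3590 ± 663 to 17478 ± 5256 (2.26, adjusted p = 0.00397), and Lin28a fell 28.7-fold from 21098 ± 644 (-4.87, SE 0.35, adjusted p = 0.000157). The largest rises were Alox12e (4.47 to 1432, 8.75), Esr1 (1.12 to 428, 7.84) and the clock gene Npas2 (3.35 to 333, 6.91). Large falls were Fndc3c1 (591 to 4.11, -6.90) and the smooth-muscle actin Acta2 (518 to 4.23, -6.69). The formative list fell, 6 of 12 fallen and 0 risen, with 6 and 1 adjusted over the list alone (median -1.77; camera adjusted p = 0.0153, adjusted p = 0.479 with an estimated correlation). Its member Pou3f1 went from 1891 to 80.2 (-4.53) and Fgf5 from 76.8 to 0 reads, at least 72.3-fold lower. Of 19 known targets 9 rose and 0 fell, 11 and 0 adjusted over the list alone (median 1.30; camera adjusted p = 0.00123, adjusted p = 0.429 with an estimated correlation). In all, 2452 genes were called (1435 higher); the count was 654 without wild-type library 2, 994 without wild-type library 1, 1407 without clone library 2 and 3933 without clone library 1, where the split turned to 1861 higher and 2072 lower. Chromosome 8 genes were higher in the clones here too, with medians of 0.32 and 0.48 in the clone libraries, and wild-type library 2 had a higher intron share (13.32%) than either clone library.

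Against B9 (n = 2 and 2), which keeps Ago2, 1719 genes were called (999 higher). Lefty1 rose from 2814 ± 191 to 25941 ± 20420 (log2 change 2.94, SE 0.49, adjusted p = 0.00547) and Lats2 from 193 ± 16.6 to 2856 ± 249 (3.88, adjusted p = 0.00017). Gap43 fell from 651 ± 195 to 4.597 (-6.84) and the endoderm factor Gata6 from 105 to 1.82 (-5.30). Of 21 Smad2/3 targets 6 rose and 0 fell, 7 and 1 adjusted over the list alone (median 0.51; camera adjusted p = 0.0183, adjusted p = 0.339 with an estimated correlation). Of 19 known targets 11 rose and 0 fell, 12 and 0 adjusted over the list alone (median 1.42; camera adjusted p = 1.04e-06, adjusted p = 0.339 with an estimated correlation). Of 13 interferon genes 5 rose and 0 fell, 7 and 0 adjusted over the list alone (median 1.92; camera adjusted p = 0.00454, adjusted p = 0.339 with an estimated correlation), for example Oas2 (135 to 807, 2.51). The count was 404 without B9 library 1, 504 without B9 library 2, 797 without clone library 2 and 3448 without clone library 1, where the split turned to 1548 higher and 1900 lower. Both clone libraries kept their higher chromosome 8 in this comparison, and B9 had -0.113 and -0.182 there against the wild-type mean. B9 library 2 had a higher intron share (15.01%) than either clone library.

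E7 and B9 against wild type compare cells with human or mouse Ago2 as their only Argonaute with cells that have all 4. Each of these genotypes is 1 line, so the tests measure the spread of libraries and not of lines. Both mutant lines are also Blm-null, so effects of Argonaute, Blm and line cannot be told apart. In E7 Plagl1 rose from 295 ± 45.7 (n = 2) to 5472 ± 818 (n = 3; log2 change 4.21, SE 0.40, adjusted p = 0.000737), Esr1 from 1.12 ± 1.58 to 255 ± 67.2 (7.12, SE 0.68, adjusted p = 0.000737), and the actin-binding Tagln fell from 1588 to 98.6 (-3.97, adjusted p = 0.000737). These calls and that of Phlda2 (2072 to 156, -3.90) held without any 1 library. Of 601 genes called 409 were higher; the count was 44 without wild-type library 2, 123 without wild-type library 1, 163 without E7 library 2, 253 without E7 library 3 and 411 without E7 library 1. Without the clones the count was 910. Without them and with the library set of low or high intron share as a term it was 2599, 1501 higher and 1098 lower. That set was drawn from the libraries tested, so counts with it as a term may be too high. Of 21 naive genes 6 rose and 0 fell, 7 and 0 adjusted over the list alone (median 0.32; camera adjusted p = 0.00132, adjusted p = 0.372 with an estimated correlation). In B9 the lymphocyte gene Rcsd1 rose from 57.8 ± 5.90 to 425 ± 10.9 (n = 2 and 2; 2.86, SE 0.35, adjusted p = 0.0221) and the keratin Krt8 fell from 2702 to 407 (-2.68, adjusted p = 0.0229). Of 13207 genes 9 were called there, 2 higher and 7 lower, with 967 at an unadjusted p below 0.05; 0 were called without wild-type library 2, 1 without B9 library 1, 1 without B9 library 2 and 8 without wild-type library 1. Without the clones 32 were called. Without them and with the library set as a term 449 were called, 286 higher and 163 lower, so neither the count nor its direction was stable. Rcsd1 was lost without wild-type library 1 or 2 (adjusted p = 0.07 and 0.238) or B9 library 1 or 2 (0.113 and 0.235), and so was Krt8 (0.108, 0.108, 0.113 and 0.235). Of 7 neuroectoderm genes limma called 0 in B9, with 4 at an unadjusted p below 0.05 and 4 fallen adjusted over the list alone (median -1.18; camera adjusted p = 7.55e-06, adjusted p = 0.045 with an estimated correlation). Known targets lay lower in B9 as a list, though limma called 0 of 19, with 2 at an unadjusted p below 0.05 and 1 fallen adjusted over the list alone (median -0.31; camera adjusted p = 0.00936, adjusted p = 0.288 with an estimated correlation).

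Removal of doxycycline for 96 h and the step from E7 to the clones shared many genes. Megf11, Krt19, Chit1 and the hyaluronidase Cemip rose both at 96 h and in clones against E7, and Lin28a, Gap43, Usp51 and Chac1 fell in both. In clones against E7 the calls of Chit1, Cemip, Megf11, Krt19 and Usp51 were lost without E7 library 2 (adjusted p = 0.0641, 0.0999, 0.199, 0.0516 and 0.0807) or clone library 2 (0.187, 0.146, 0.236, 0.0521 and 0.0518), and those of Chit1 and Megf11 also without E7 library 1 (0.0605 and 0.117). Chac1 was lost without E7 library 1 (0.0996), E7 library 2 (0.156) or clone library 2 (0.0973). Of 186 genes called in both, 182 had the same sign (97.85%): 93 were higher in both (31.2 by chance), 89 lower in both (34.5 by chance), and 4 changed in opposite directions. Across 13151 genes, which are not independent replicates, the rank correlation of the 2 changes was 0.506, and 0.404 without E7 library 1. With clones against wild type it was 0.661, with E7 against wild type 0.463 and with B9 against wild type 0.082. Of 510 genes called both at 96 h and in E7 against wild type, 90.78% had the same sign, so the sharing extends to cells that keep human Ago2 and is not specific to loss of the last Argonaute. Changes at 96 h reversed in the rescue: across 13149 genes the rank correlation with 2.5 µg/mL against no doxycycline was -0.794, with 3230 genes higher and then lower (1397 by chance) and 3198 lower and then higher (1389 by chance). Of the 198 genes called in clones against E7, 191 had the opposite sign in the rescue at 2.5 µg/mL; over all 12959 genes 35.23% had the same sign, with a rank correlation of -0.452. The rescue libraries at 2.5 µg/mL had the lower intron share given above, and chromosome 8 was higher in the clones. At 0.1 µg/mL intron shares (12.35 and 12.47%) lay near those without doxycycline (12.21 and 11.97%). There the rank correlation with 96 h was -0.78, and 91.81% of genes called at 96 h had the opposite sign. The reversal was thus also present without that difference in intron share. Doxycycline itself ran in opposite directions in the time course and the rescue, so the reversal cannot set it apart from Ago2.

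**Figure D3:**
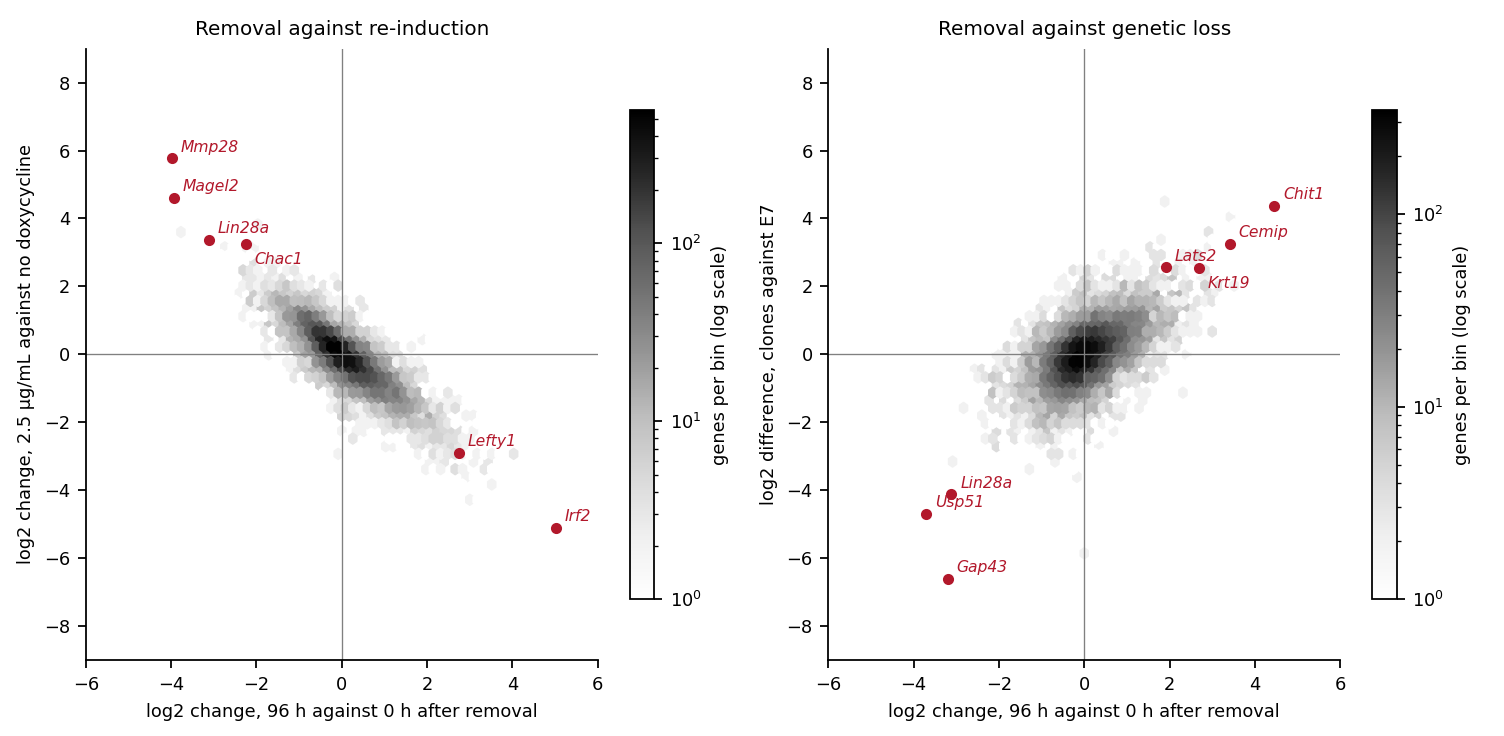
Log2 change at 96 h against that of the rescue at 2.5 µg/mL (left) and of clones against E7 (right) across genes, with selected genes labelled in red.

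Genes with a seed site of miR-290 and miR-302 in their 3' UTR (2758, against 10774 without) rose at 96 h by 0.17 more than genes without (camera adjusted p = 0.00584 over 9 families), and those with an 8-mer site by 0.31. In introns the shift was -0.02, and in exon minus intron it was 0.18 (camera adjusted p = 5.15e-06). It was 0.06 at 24 h (camera adjusted p = 0.337) and 0.15 at 48 h (camera adjusted p = 0.00538). In the rescue it was -0.13 at 0.1 µg/mL (camera adjusted p = 0.000179) and -0.25 at 2.5 µg/mL (camera adjusted p = 4.01e-05). At the higher dose, in the libraries of lower intron share, the introns moved too, by -0.15 (camera adjusted p = 0.0459), and exon minus intron did not pass (-0.10, camera adjusted p = 0.261). Among other families at 96 h, miR-17 sites gave 0.13 (camera adjusted p = 0.0143) and miR-130 sites 0.12 (camera adjusted p = 0.048), while miR-19 (0.11), miR-25 (0.10) and miR-15 (0.05) did not pass. Of the controls let-7 gave 0.03, miR-122 0.04 and miR-124 0.09 (camera adjusted p = 0.405, 0.349 and 0.168). In clones against E7 the miR-290 shift was 0.02 (camera adjusted p = 0.997), 0.0728 matched on 3' UTR length and 0.108 with 8-mer sites (camera adjusted p = 0.0841), so a shift there is neither shown nor excluded; it was 0.161 without clone library 2, and -0.0934 without clone library 1 and -0.0128 without E7 library 1. Single genes that rose more in exons than introns at 96 h included Lats2 (1.96), the growth factor Gdf11 (2.19) and the connexin Gja4 (2.21), and those that fell more included the cytokine Lif (-2.61) and Fut2 (-3.70). Exon minus intron called 1084 genes at 96 h, but 14 and 1 without 0 h library 1 and 2, and 0 without either 96 h library, so these single calls rest on all libraries.

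**Figure D4:**
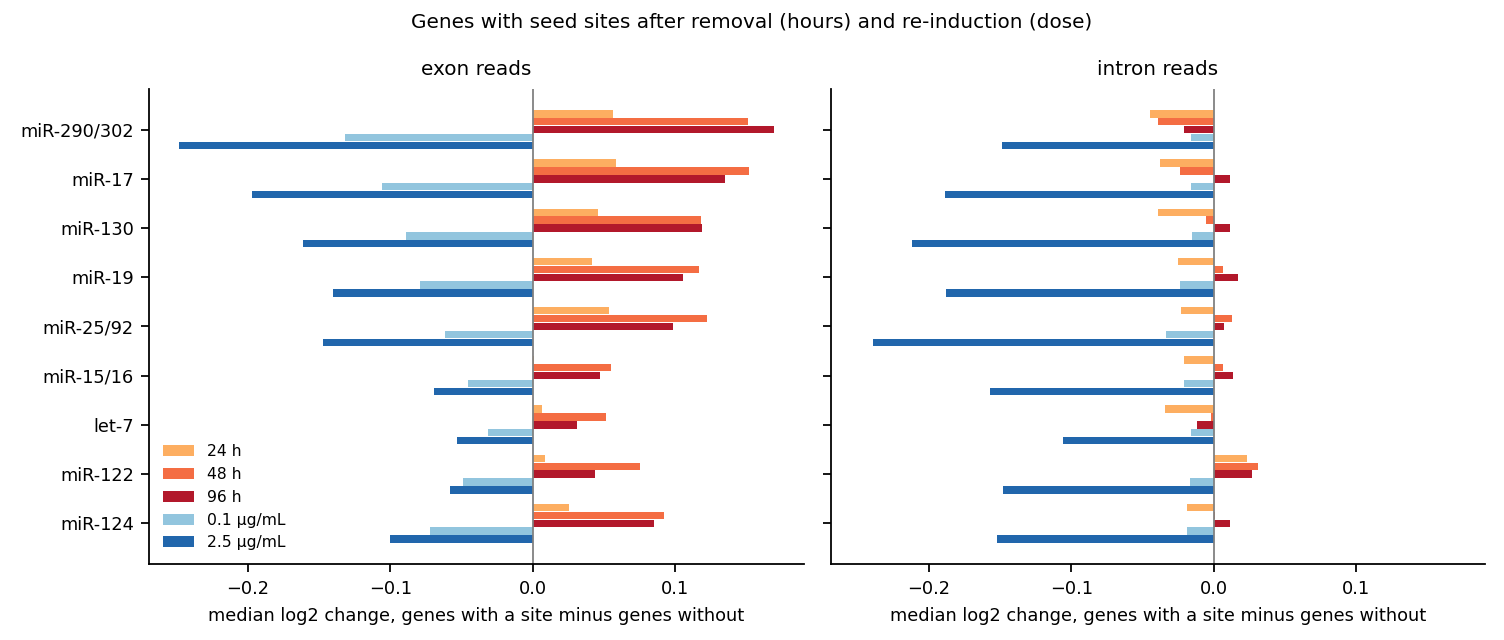
Seed-site shift of 9 microRNA families in exons (left) and introns (right) at 24, 48 and 96 h of loss and at 0.1 and 2.5 µg/mL in the rescue.

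Genes of chromosome 8 were compared with the others because several genes named above lie there. In clones against E7 their median log2 difference from other chromosomes was 0.344 in exons and 0.3536 in introns, against 0.0653 for the next highest chromosome. Set against the wild-type mean, chromosome 8 stood at 0.32 and 0.48 in the clone libraries, and at 0.28 in E7 library 1. The Y-linked genes Ddx3y, Eif2s3y and Uty had 2, 0 and 0 reads in clone library 1, and 987, 616 and 324 normalised reads in clone library 2. In wild type Ddx3y had 2134 and 2052.

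**Figure D5:**
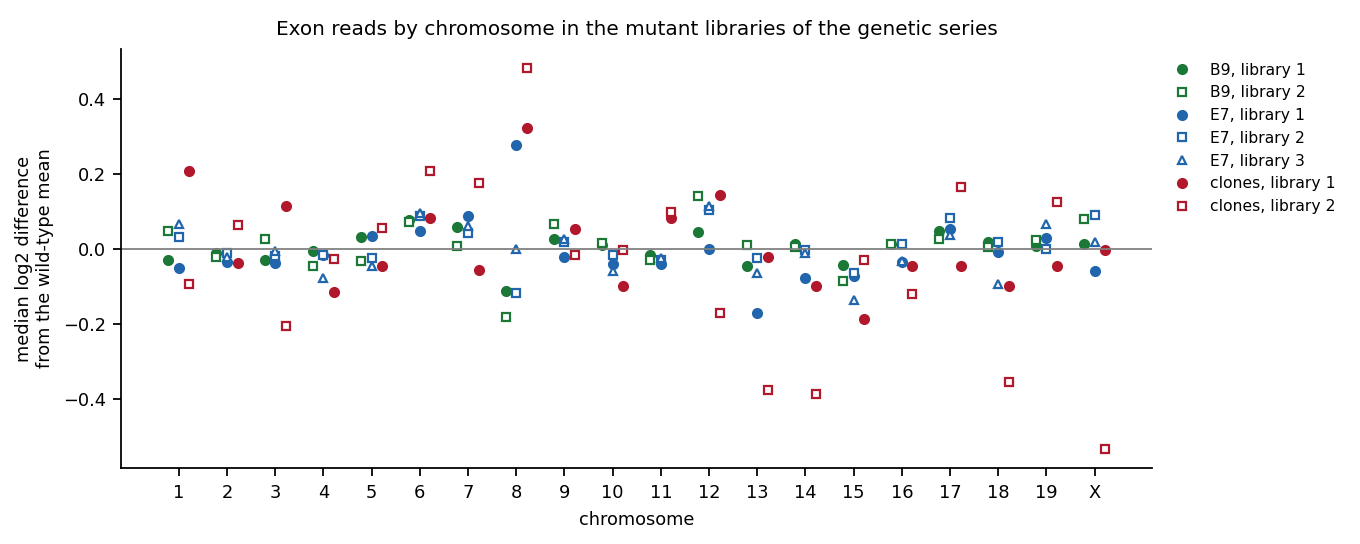
Median log2 difference from the wild-type mean by chromosome for each library of B9, E7 and the clones.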

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

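Of the tests below, the one on genes called both at 96 h and in clones against E7 was chosen after its result was seen.

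The rise of genes with miR-290 seed sites at 96 h was weighed against 3 technical explanations. Matching on 3' UTR length left 73.13% of the shift (95% bootstrap interval over genes 62.29 to 90.19%), which argues against length as its whole cause. In introns the same genes had a shift of -12.15% of that in exons (-31.58 to 5.118%). This argues against a change in transcription as the source of the rise at 96 h. The test did not cover the rescue. At the higher dose there the intron shift was negative like that in exons, and exon minus intron did not pass. A change in transcription was thus not excluded for that comparison, in which intron share differed as well. Sequence features shared by any seed site cannot be told apart from microRNA targeting here, since the largest control shift, that of miR-124, was 50.36% of the miR-290 shift (35.92 to 66.72%), an interval that spans the bound of 50% set for it. Loss of silencing by Argonaute, the difference the design names, stays open as a hypothesis and was not tested apart from doxycycline in this series.

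The changes 96 h after doxycycline removal were weighed against doxycycline acting apart from Ago2. Longer culture than at 0 h, another difference by the labels, was not tested. Of all genes called at 96 h, 73.46% had the same sign in clones against E7, where no doxycycline differs (67.96 to 77.9% over leaving out 1 library), a range that reaches below the bound of 70%, so doxycycline and loss of Ago2 cannot be told apart for this wider set. Of genes called in both comparisons, 97.85% had the same sign (exact interval 94.59 to 99.41%, which treats genes as independent). This share lay above the bound of 70%, which argues against doxycycline apart from Ago2 as the only cause for these 186 genes. Genes called both at 96 h and in E7 against wild type, where human Ago2 is kept and no doxycycline differs, shared their sign in 90.78%. Of all genes called at 96 h, 74.78% had the same sign in E7 against wild type and 53.41% in B9 against wild type. Agreement in sign is thus not particular to loss of the last Argonaute. The test therefore does not show that loss of Ago2 caused the changes in these 186 genes. Mitochondrial translation stress, which doxycycline may relieve when it is removed, cannot be told apart from loss of Ago2 for the integrated stress response list: its median was -0.8889 at 96 h, and it was also lower in clones against E7 (camera adjusted p = 0.00109), a call lost without clone library 1 (adjusted p = 0.654), with an estimated correlation (adjusted p = 0.787) and with fry (adjusted p = 0.247).

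A further set of genes and lists was picked out because their change from 0 h differed between 24 and 96 h, in a limma test of the difference itself that reduces to 96 h against 24 h. In all, 315 genes were higher at 24 h and lower at 96 h, and 301 the reverse. The glutathione transferase Mgst1 differed by -3.18 (log2), with means of 44.7, 122, 82.8 and 12.8 at 0, 24, 48 and 96 h, and the acyl-CoA thioesterase Acot3 by -3.31 (49.2, 134, 106 and 12.9). Susd5 differed by -2.99 (59.2, 178, 102 and 21.8), the insulin receptor substrate Irs1 by -2.53 (34.6, 85.8, 77.0 and 14.7) and Plppr3 by -2.28 (58.9, 127, 175 and 25.8). In the other direction the homeobox gene Evx1 differed by 4.72 (91.5, 12.9, 65.2 and 348), the prostaglandin transporter Slco2a1 by 2.61 (152, 53.7, 101 and 327) and Maats1 by 2.35 (124, 56.1, 98.1 and 290). Lrrk1 differed by 2.46 (41.7, 20.6, 57.7 and 113) and Creb5 by 2.16 (53.1, 26.1, 86.1 and 118). Each of these groups had 2 libraries.

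Lists that differed between 24 and 96 h were known targets of ES-cell microRNAs (median difference 0.85; camera adjusted p = 1.02e-09, adjusted p = 0.0481 with an estimated correlation) and Smad2/3 targets (0.47; adjusted p = 2.82e-05, adjusted p = 0.229 with an estimated correlation). The 2-cell-like list (1.22; adjusted p = 0.000726, adjusted p = 0.229 with an estimated correlation), interferon genes (0.50; adjusted p = 0.0313, adjusted p = 0.244 with an estimated correlation) and G1/S regulators (0.22; adjusted p = 0.0209, adjusted p = 0.424 with an estimated correlation) were also higher at 96 h. Immediate early genes were higher too (0.65; adjusted p = 0.00171, adjusted p = 0.227 with an estimated correlation). Lower at 96 h than at 24 h were the imprinted list (-0.48; adjusted p = 0.0329, adjusted p = 0.378 with an estimated correlation) and the glycolysis and hypoxia list (-0.55; adjusted p = 5.88e-08, adjusted p = 0.47 with an estimated correlation).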

How the results depend on the processing

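Chosen after the data were seen were limma-voom, fits without libraries of high or low intron share, fits without the clones or without chromosomes 8 and Y, and the other match of exon and intron libraries. The library set as a term, also chosen then, was fitted without the clones. No paired analysis was possible because the deposited columns carry no replicate number, so the replicate block was not run; the library set stood in for it as a block found from the data. The count tests of edgeR and DESeq2 were not run, since the deposited unit is a group mean and not counts. Where leaving out a library left a group with 1, that library was assumed to vary like the other groups. For results that moved with a setting the cause was not tested, save for the 2-fold threshold, which can only lower a count.

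Clones against E7 called 198 genes in exons and 15 in introns. With only the libraries compared the counts were 57 and 58. Without libraries of high intron share they were 95 and 3, and without those of low intron share 7 and 46; limma-voom called 7 in introns. The split of 94 higher and 104 lower became 187 and 89 with limma-voom and 157 and 115 with 8 added. Without genes of chromosomes 8 and Y, 181 were called, and all 181 were shared with the 198. Leaving out 1 library gave 15 (E7 library 2) to 2146 (clone library 1) in exons and 2 to 74 in introns.

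Clones against wild type called 2452 genes, 610 without libraries of high and 474 without those of low intron share, and 654 to 3933 without 1 library. Clones against B9 called 1719, 1065 with only the libraries compared, 486 and 106 without libraries of high and of low intron share, and 404 to 3448 without 1 library. E7 against wild type called 601, 910 without the clones, and 44 to 411 without 1 library. Without the clones and with the library set as a term it called 2599 (1501 higher, 1098 lower). B9 against wild type called 9 (2 higher, 7 lower), 15 with 8 added, 1 with no filter, 23 with quantile normalisation (11 higher, 12 lower) and 15 with limma-voom. It called 4 with only the libraries compared and 32 without the clones. Without the clones and with the library set as a term it called 449 (286 higher, 163 lower). Fewer than 9 were called when any 1 library was left out.

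At the 2-fold threshold 803 of 6919 genes remained at 24 h, 1415 of 8642 at 48 h, 1829 of 8867 at 96 h, and 1300 of 7818 for 96 h against 24 h. In the rescue it left 496 of 5808 at 0.1 µg/mL, 1883 of 8400 at 2.5 µg/mL and 491 of 5403 between the doses. In introns it left 1241 of 5449 at 96 h and 1713 of 5377 at 2.5 µg/mL. Leaving out 1 library gave 5556 to 6062 genes at 24 h, 7370 to 7794 at 48 h, 7955 to 8338 at 96 h and 6731 to 7038 for 96 h against 24 h. In the rescue it gave 4275 to 4765 at 0.1 µg/mL, 7200 to 7807 at 2.5 µg/mL and 4172 to 4946 between the doses. In introns it gave 4301 to 4404 at 96 h and 4008 to 5203 at 2.5 µg/mL. Near-even splits turned with some settings, for example to 3353 higher and 3437 lower at 24 h with quantile normalisation.

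Exon minus intron called 1084 genes at 96 h, 327 with no filter, 1721 at a mean of at least 50 and 551 with libraries matched the other way, and 0 to 14 without 1 library. At 2.5 µg/mL it called 1280, 0 with no filter, 2174 at a mean of at least 50, and 0 without any 1 library. In clones against E7 it called 0, with 772 at an unadjusted p below 0.05, and 0 to 1 without 1 library.

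The miR-290 shift in clones against E7, 0.02, was 0.0728 matched on 3' UTR length and 0.108 with 8-mer sites, and -0.0128 without E7 library 1 and -0.0934 without clone library 1, where its sign reversed; its highest value was 0.161. Leaving out 1 library gave 0.153 to 0.181 at 96 h and -0.253 to -0.235 at 2.5 µg/mL. The correlation across genes of 96 h with clones against E7, 0.506, was 0.438 in introns, 0.513 without chromosomes 8 and Y, and 0.404 to 0.574 without 1 library. The reversal in the rescue, -0.794, was -0.802 with 8 added, -0.820 at a mean of at least 50, -0.828 as Pearson r, -0.522 in introns and -0.785 to -0.773 without 1 library.

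With an estimated correlation 0 lists passed camera in clones against E7, 1 at 96 h and 0 at 2.5 µg/mL, while fry passed 0, 21 and 21. Without 1 library camera passed 0 to 6, 10 to 13 and 7 to 8 lists. Each call of a named gene was refitted in several settings. Of these refits 6018 were the same and 403 weaker across the alternatives, and 3294 the same and 700 weaker across libraries left out. Counted by call, 978 were the same in at least 1 alternative and 197 weaker in at least 1. With libraries left out, which mostly leaves 1 library in a group, these counts were 928 and 266.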

Other observations

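Of the tests below, the one on chromosome 8 was chosen after the result was seen, as was the comparison of libraries by intron share.

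Some lists at 24 and 48 h are given here; 48 h was not tested against 24 or 96 h. At 48 h 19 of 21 cholesterol genes had risen from 0 h and 0 had fallen, the same adjusted over the list alone (median 0.58; camera adjusted p = 1.06e-09, adjusted p = 0.262 with an estimated correlation), and the sterol regulator Insig1 went from 3354 at 0 h to 5993, 8621 and 5308 at 24, 48 and 96 h. Of 10 genes of the 2-cell-like list 0 rose and 3 fell at 24 h, the same adjusted over the list alone (median -0.19; camera adjusted p = 0.393), 2 rose at 48 h (0 adjusted over the list alone) and 9 at 96 h. The median of 96 h against 24 h, 1.22, thus exceeded that against 0 h, 0.94. Zscan4f, which marks that state, had 467 at 0 h, 512 at 24 h (not called), 568 at 48 h and 1174 at 96 h (n = 2 each). Immediate early genes fell at 24 h, 7 of 15 fallen and 4 risen, 9 and 4 adjusted over the list alone (median -0.51; camera adjusted p = 0.0266, adjusted p = 0.266 with an estimated correlation), with Egr1 down from 5384 to 2299 (-1.23).

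Genes of pluripotency and imprinting were mixed by genotype. In clones against wild type 6 of 21 naive genes rose and 1 fell, 7 and 1 adjusted over the list alone (camera adjusted p = 0.0502), and 1 of 14 imprinted genes rose and 7 fell, 3 and 7 adjusted over the list alone (camera adjusted p = 0.0654). The imprinted Peg10, left out of tests in the genetic series, had a mean of 35991 in wild type and 5654 in the clones. The naive factors Klf2 and Prdm14 were higher in the clones than in wild type (7236 to 36640, log2 change 2.35, adjusted p = 0.00105, and 518 to 2449, 2.26, adjusted p = 0.0027; n = 2 and 2). Klf2 fell in the rescue at 2.5 µg/mL (43625 to 20029, -1.12) and so did Prdm14 (2457 to 1004, -1.29). The imprinted Plagl1, high in E7, was also higher in the clones than in wild type (295 to 12406 ± 9433, 5.15, adjusted p = 0.00026), with the clone libraries far apart. In the rescue Plagl1 fell from 14213 to 4017 (-1.82). Phlda2, an imprinted brake on placental growth, moved the other way, from 2072 in wild type to 40.8 in the clones (-5.67, adjusted p = 0.000282), and rose in the rescue from 75.5 to 405 (2.43). In the rescue these changes go with the lower intron share of the 2.5 µg/mL libraries, and Klf2 lies on chromosome 8, whose genes were higher in the clones as a whole. In E7 against wild type the trophoblast list fell, 4 of 9 fallen and 0 risen, with 4 and 1 adjusted over the list alone (median -0.88; camera adjusted p = 0.023, adjusted p = 0.41 with an estimated correlation).

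Genes of chromosome 8 were higher in the clones than in E7. An extra copy of chromosome 8 in part of the cells cannot be told apart from other causes, since 6 of 7 stretches of 20 Mb had a median above 0 in each clone library, the exception being 40 to 60 Mb with -0.15 in library 2 over 48 genes. The biological difference named by the design, loss of the last Argonaute, was not tested as a cause of this pattern. Without genes of chromosomes 8 and Y the clones differed from E7 at 181 genes in place of 198.

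Y-linked genes set the clone libraries apart. Clone library 1 had 2 reads of Ddx3y and 0 of Eif2s3y and Uty, while clone library 2 had 740, 462 and 243. Clone library 2 was lower than wild type on chromosome 13 (-0.38), chromosome 14 (-0.39), chromosome 18 (-0.35) and X (-0.53). No explanation of these differences was tested.

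Libraries of wild type, B9 and E7 fell in a set of low intron share, 8.681 to 9.669% (wild-type library 1, B9 library 1 and E7 library 1), and one of high intron share, 13.21 to 15.01% (wild-type library 2, B9 library 2 and E7 libraries 2 and 3). The clone libraries, at 10.46 and 7.489%, lay outside both ranges and below the high set, so intron share goes partly with the clone comparisons. The labels give no batch. The shares rest on the match of exon and intron libraries; matched the other way, B9 libraries 1 and 2 would have 13.90 and 9.722%. In exon reads alone, which need no match, deviations from the group mean correlated across genes at 0.301 to 0.504 between groups within these sets, save for E7 library 2. That library correlated at -0.0598 with wild-type library 2 and -0.087 with B9 library 2, so exon reads do not bear out its place in the high set. In groups of 2 libraries the deviations mirror each other, so agreement in 1 set largely repeats that in the other. A difference in library preparation is a candidate source of this split. In B9 against wild type 9 genes were called, 32 without the clones, and 449 without them and with the library set as a term. In E7 against wild type these counts were 601, 910 and 2599. Which sample each library is could not be worked out, so the source of the split stays open.

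Gene-wide reads of Ago2 stayed near the wild-type level in the clones. In TT-FHAgo2 cells they fell slightly 96 h after doxycycline was removed (log2 change -0.15) and were also lower at 2.5 µg/mL than without it (-0.36). Intron reads of Ago2 were higher in E7 and the clones than in wild type. Reads over the deleted exons and the transgene were not analysed here, so the amount of functional Ago2 in each group was not measured.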
